A study of Mus musculus with 6 samples.

How the data were processed

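RNA was sequenced from whole hearts of 15-day-old mice, 3 of the Nat10 flox genotype and 3 labelled as a heart-muscle-specific knockout (CKO). Per the labels' protocols, total RNA was extracted with Tripure reagent, messenger RNA was captured on poly-T beads and fragmented, complementary DNA was primed with random hexamers, and libraries were read as paired ends of 150 bases on a NovaSeq instrument. Whether the libraries keep strand is not given in the sources used here. Each group holds 3 independent biological replicates, per the labels.

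The submitters' processing notes list CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, and the series text gives the GRCm38 (mm10) mouse genome. The authors deposited FPKM values (fragments scaled by gene length and library size) for 54532 genes in 1 column per heart, with a gene length in bases for each gene. How the authors set the library size behind the FPKM is not given in the sources used here, but the values show it. FPKM multiplied by gene length was a whole multiple of 1 step per library for 100% of the values above 0, within a tolerance of 0.01, and the counts recovered this way summed to between 15048038 and 16280061 per heart. The library size implied by that step was the median-of-ratios size factor multiplied by the geometric mean of the totals, with a ratio of 1 in each of the 6 libraries. The deposited FPKM are thus already scaled between hearts by median ratios, and size factors ran from 0.893 to 1.07. Of the gene identifiers, 99.8% were found in GENCODE M21, which was used only for the GC content of each gene's longest transcript. Genome positions are those of the deposited table.

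Expression was tested on log2(FPKM + 1), so that fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. Genes with a mean FPKM of at least 1 over the 6 hearts were kept, 12469 in all. A linear model with genotype as its only term was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend. Benjamini-Hochberg adjusted p-values were two-sided, and genes under 0.05 were called. Beyond the threshold, a change of at least 2-fold was counted separately. Errors of log2 changes are standard errors of the limma fit, and levels are given as mean ± SD over 3 hearts. Single genes were also compared by an exact two-sided permutation test, which for 3 hearts against 3 cannot give a p below 0.1. A gene at 0 in every heart of 1 group was compared with a floor of 3 counts per library, and its fold is given as a lower bound.

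Before the data were examined, 40 gene lists (pathways, cell type markers and 1 check on sex) were fixed. They held 680 symbols, of which 679 were found. Lists of the first 2 kinds with at least 5 measured members, 31 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run as alternatives. Also fixed at that point was the rule for named genes. It took Nat10, Nppa, Nppb, Myh6, Myh7, Atp2a2, Gdf15 and Cdkn1a whatever their result, and the 8 largest rises and 8 largest falls among called protein-coding genes whose groups did not overlap, without predicted genes. From each list it took up to 3 called members with the largest change, or, where none was called, the member with the highest mean FPKM. Members of lists that are only counted were not all named. Sesn1, Pfkm, Ldhb, Acta1, Uchl1 and Tnni1 were named after their values were seen. The result of 1 gene that the rule takes is not reported here.

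The procedure was tested on simulated data for the comparison of CKO with flox hearts over 12469 genes. Of 100 genes changed 2-fold, 20 were called, and of 100 changed 4-fold, 83 were called, with 0 in the wrong direction. Of 12269 unchanged genes, 3 were called. Far fewer genes were changed here than were called in the data, so these shares need not hold for the data. A list shifted 1.5-fold was called, and so was 1 of 30 other lists. Genes were simulated independently of each other, while genes of a list can vary together in real hearts. The list result therefore does not show how often camera calls unchanged lists in the data.

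Alternatives planned before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a minimum mean FPKM of 5, protein-coding genes only, TPM, median-ratio and quantile normalization, limma without a trend or with robust moderation, array weights, the replicate number as a block, voom on the recovered counts, and each heart left out in turn. Scaling by total counts and removal of trends with gene length or GC content (loess, span 0.3) were added after the data were seen. Sex as a covariate was not run, because every heart had male expression.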

Results

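Whole-heart messenger RNA was profiled in 15-day-old mice of 2 genotypes, 3 hearts each. Control mice carried Nat10 with recombination sites (flox), and the other mice were labelled as lacking Nat10 in cardiomyocytes (CKO). Which part of the gene the sites flank is not given in the sources used here. Nat10 encodes an acetyltransferase that places acetylcytidine on RNA and takes part in ribosome production. The series asks how its loss affects the developing heart. Recovered counts ran from 15048038 to 16280061 per heart, and 12469 genes had a mean of at least 1 FPKM. All 6 hearts had male expression, with Ddx3y at 15.5 to 18.4 FPKM and Xist at no more than 0.0339 FPKM. On the first principal component, which held 64.0% of the variance, the 3 flox hearts lay between −38.7 and −19.1 and the 3 CKO-labelled hearts at 14.9 or above. CKO replicate 1 lay farthest out, and its profile correlated with the flox hearts at 0.876 to 0.912 across genes.

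Nat10 itself (ENSMUSG00000027185, chromosome 2, 103721256 to 103761270, GRCm38) was not lower in the CKO-labelled hearts. Its level was 3.87, 3.78 and 4.57 FPKM in flox replicates 1, 2 and 3, and 3.69, 3.75 and 4.18 FPKM in CKO replicates 1, 2 and 3. The log2 change was −0.06 ± 0.12 (SE, n = 3 per group, limma adjusted p = 0.768; exact permutation p = 0.5, smallest possible 0.1), with a 95% interval from −0.33 to 0.22. On the scale of FPKM + 1, a fall by more than 20.3% lay outside that interval. A deletion usually removes only some exons, and whole hearts hold other cells that keep the gene, so the value neither verifies nor contradicts the genotype labels. The directions below are therefore given for hearts labelled CKO.

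The CKO-labelled hearts differed broadly from the flox hearts, with Nppa, Gdf15, Sprr1a and Cdkn1a among the largest rises and Art1, Kcnip2, Asb15 and Rpl3l among the largest falls. limma called 1761 genes, 864 higher and 897 lower, and 666 of them changed at least 2-fold, 331 up and 335 down. The groups did not overlap for 4940 genes (39.6%). Over the 10 possible splits of the hearts this share averages about 10% by construction. Genes vary together, so the contrast is not a test. Scaling moved the balance of the calls. With TPM, 69.0% of the called genes were higher, and with scaling by total counts 66.4%, against 49.1% with the deposited scaling, because the median of all genes moved up by 0.13 and 0.11 on the log2 scale. The number called fell to 364 without flox replicate 1, to 478 without flox replicate 2 and to 755 without CKO replicate 3. It was 1426 without CKO replicate 1, the library that stood apart. Those called at least 2-fold numbered 307 without flox replicate 1 and 372 without flox replicate 2.

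**Figure D1:**
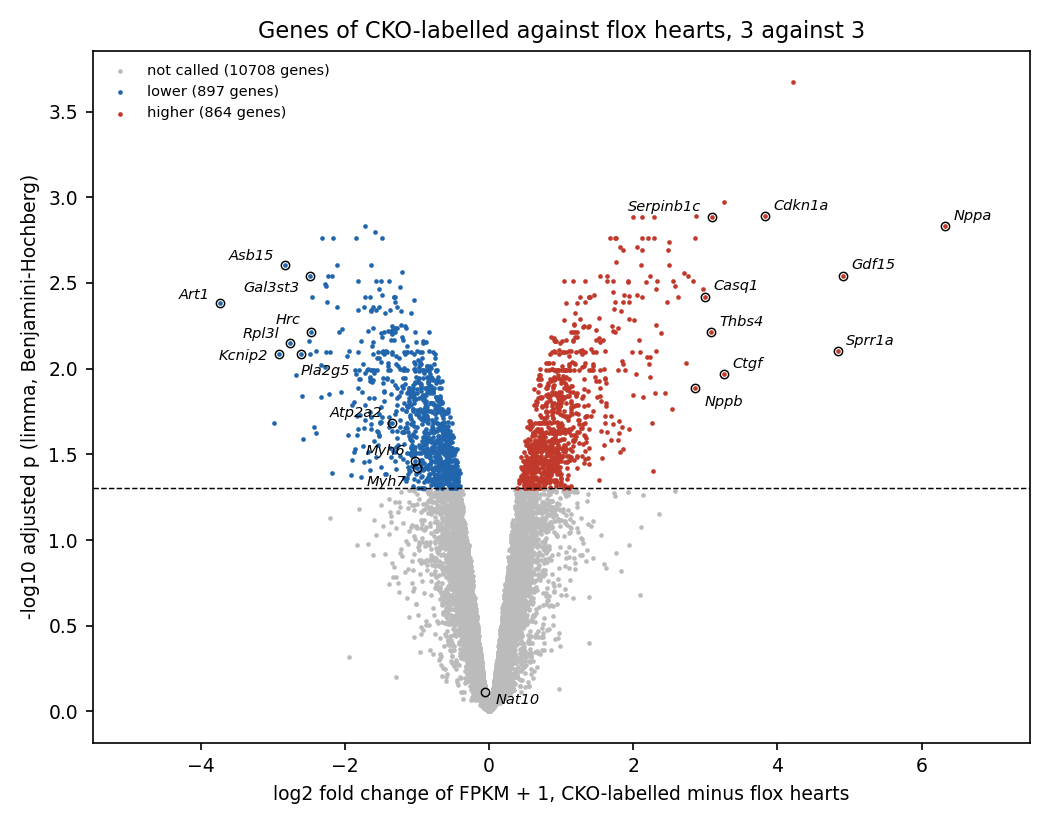
Each point is 1 of 12469 genes, with the log2 fold change of FPKM + 1 (CKO-labelled minus flox hearts, 3 each) on the x axis and −log10 of the limma adjusted p on the y axis. The dashed line marks 0.05, and circles mark genes named by the fixed rule. Nppa lies farthest right at 6.33 and Art1 farthest left at −3.73, while Nat10 lies near 0. The position of Sprr1a depends on the pseudocount, because its flox hearts were at 0.

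Stress and fetal genes of the heart muscle rose most as a list, although not every member rose. Nppa, which encodes atrial natriuretic peptide (chromosome 4, 148000722 to 148002079), went from 21.9 ± 12.7 FPKM in flox to 1696 ± 609 FPKM in CKO-labelled hearts (SD, n = 3), a log2 change of 6.33 ± 0.45 (SE, limma adjusted p = 0.00148). Nppa is also on the atrial muscle list given below, and the share of atrial tissue in each heart was not tested. Nppb, the gene of B-type natriuretic peptide, rose from 182 ± 89.5 to 1295 ± 632 FPKM (log2 change 2.85 ± 0.48, limma adjusted p = 0.0129). Gdf15, a secreted stress factor (chromosome 8, 70629393 to 70632456), rose from 1.52 ± 1.13 to 76.7 ± 40.5 FPKM (4.91 ± 0.47, limma adjusted p = 0.00286), and Ctgf, a matrix-associated growth factor, rose by a log2 change of 3.26 ± 0.52 (limma adjusted p = 0.0108). Of the 15 measured genes of the fetal and stress list, 11 rose, 1 fell and 3 were not called, and the counts adjusted over the list alone were also 11 and 1. The 3 not called were Acta1 (log2 change 1.19), Uchl1 (0.63) and Tnni1 (−0.68). The list's median log2 change was 1.98 (camera adjusted p = 1.8e-08; adjusted p = 0.423 with an estimated correlation). The member that fell was Myh7, the slow myosin heavy chain, at 72.6 ± 22.6 against 34.8 ± 5.03 FPKM (0.501-fold, SE of the log2 change 0.25, limma adjusted p = 0.0378). Its sequence is close to that of Myh6 and it overlaps antisense genes, so its reads are uncertain, and the call was lost in 5 of the 6 fits without 1 heart, with adjusted p up to 0.137 (flox replicates 1 and 2 and CKO replicates 1, 2 and 3).

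Sprr1a, a cornified-envelope gene also known from stressed heart muscle, had 0 counts in the 3 flox hearts and 42.7 ± 49.4 FPKM in the CKO-labelled hearts, at least 174-fold higher against a floor of 3 counts per library, and at least 58-fold without CKO replicate 1. The other large rises were Serpinb1c, a serine protease inhibitor gene with close paralogs (log2 change 3.09 ± 0.21), Thbs4, a matrix glycoprotein gene (3.08 ± 0.39), and Casq1, which encodes the calcium-binding calsequestrin of skeletal muscle (3.00 ± 0.33). Among the 8 largest falls were Art1, an ADP-ribosyltransferase gene that overlaps Art5 (−3.73 ± 0.42), Asb15, a muscle ubiquitin-ligase adaptor (−2.83 ± 0.25), Pla2g5, a secreted phospholipase (−2.61 ± 0.37), Gal3st3, a sulfotransferase (−2.49 ± 0.24), and Hrc, a calcium-binding protein of the sarcoplasmic reticulum (−2.47 ± 0.31). The calls of these 9 genes held without each heart in turn, with limma adjusted p of at most 0.0370.

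Target genes of p53, the transcription factor of the DNA damage and growth-arrest response, rose together. Cdkn1a, a cell cycle inhibitor (chromosome 17, 29090976 to 29100727), went from 13.3 ± 3.78 to 199 ± 39.7 FPKM (SD, n = 3; log2 change 3.82 ± 0.23, limma adjusted p = 0.00129). Phlda3 rose by a log2 change of 2.70 ± 0.25 and Eda2r by 2.49 ± 0.23. Of 20 measured targets, 15 rose, 1 fell and 4 were not called, with 18 and 1 adjusted over the list alone. The median change was 1.27 (camera adjusted p = 2.3e-12; adjusted p = 0.363 with an estimated correlation). The member that fell was Sesn1, at a log2 change of −1.03, chosen after its value was seen. Calls of Cdkn1a, Phlda3 and Eda2r held without each heart in turn.

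Genes for building ribosomes were also higher. Of 28 measured ribosome biogenesis genes, 16 rose and 12 were not called, against 24 up and 1 down adjusted over the list alone. Examples were Rrp12, a processing factor of the small subunit (6.36 ± 2.39 against 23.6 ± 1.90 FPKM, log2 change 1.79 ± 0.22, limma adjusted p = 0.00577), Nhp2, a small nucleolar RNA-binding protein (1.35 ± 0.29), and Wdr43 (0.98 ± 0.19). The median change of this list was 0.71 (camera adjusted p = 1.1e-09; adjusted p = 0.423 with an estimated correlation). Among 26 genes of cytosolic ribosomal proteins, 19 rose, 1 fell and 6 were not called, with 23 and 1 adjusted over the list alone, at a median change of 0.89 (camera adjusted p = 1.3e-09; adjusted p = 0.423 with an estimated correlation). Rps12 rose from 30.5 ± 5.30 to 86.0 ± 35.2 FPKM (1.41 ± 0.27, limma adjusted p = 0.0189) and Rps27l, which is also a p53 target, rose by 1.70 ± 0.21. The gene that fell was Rpl3l, the striated-muscle form of Rpl3, at 30.2 ± 17.1 against 3.19 ± 0.770 FPKM (−2.76 ± 0.37, limma adjusted p = 0.00705). Ribosomal protein genes have many processed pseudogenes, so their read counts are uncertain. Calls of Nhp2 and Rps12 were lost without flox replicate 1 or flox replicate 2, and that of Wdr43 also without CKO replicate 3 (adjusted p up to 0.0984).

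Matrix and fibrosis genes were higher as a group. Col8a1, a collagen of vessel walls, went from 3.89 ± 0.361 to 35.6 ± 12.5 FPKM (log2 change 2.86 ± 0.23, limma adjusted p = 0.00172), Tgfb2, a growth factor of the TGF-beta family, rose by 2.50 ± 0.21 and Thbs4 by 3.08 ± 0.39. Of 26 measured members, 15 rose and 11 were not called, with 21 up adjusted over the list alone, at a median change of 1.10 (camera adjusted p = 1.7e-12; adjusted p = 0.363 with an estimated correlation). In the inflammation and acute phase list, 4 of 13 measured genes rose and 9 were not called (6 up adjusted over the list alone), at a median of 0.59 (camera adjusted p = 0.00233; adjusted p = 0.423 with an estimated correlation). Lgals3, a galectin gene, rose by 2.13 ± 0.38, Vcam1 by 0.74 ± 0.13 and Osmr by 0.73 ± 0.14. The calls of Lgals3 and Vcam1 were lost without flox replicate 1 or flox replicate 2, and that of Osmr also without CKO replicate 3, with adjusted p of up to 0.0723.

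Cell type markers did not move as one. Cardiomyocyte markers were lower, with 7 of 12 fallen and 5 not called (9 adjusted over the list alone) at a median change of −0.81 (camera adjusted p = 8.7e-06; adjusted p = 0.423 with an estimated correlation). Macrophage and monocyte markers had a median of 0.42, with Cd68 alone called of 12 (0.65 ± 0.16, limma adjusted p = 0.0346; 2 adjusted over the list alone). That list passed (camera adjusted p = 0.0201; adjusted p = 0.423 with an estimated correlation), and was not called without flox replicate 2 (adjusted p = 0.0506) or with a filter of 5 FPKM (adjusted p = 0.0970). The 12 endothelial markers had 0 called by limma (2 at an unadjusted p under 0.05) and a median of −0.22 (camera adjusted p = 0.0782). Of 12 fibroblast markers, Mfap5 (1.39 ± 0.34), Tcf21 (1.01 ± 0.20) and Col1a1 (0.87 ± 0.16) rose, while the list's median was −0.07, its mean 0.17, and it was not called (camera adjusted p = 0.562). Of 11 smooth muscle and pericyte markers, Abcc9 (−1.27 ± 0.27) and Vtn (−1.18 ± 0.25) fell, and the list was not called (camera adjusted p = 0.132). Among 9 atrial muscle markers, 3 rose, of which Nppa rose most, and 1 fell, Tbx5, at −0.92 ± 0.21 (median 0.49, camera adjusted p = 0.222). Without flox replicate 2 the atrial list was called (median 0.88, adjusted p = 0.0158). The 8 erythroid markers had 0 called by limma, and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.569). The calls of Cd68, Tbx5, Abcc9, Vtn, Tcf21, Mfap5 and Col1a1 were each lost without flox replicate 1 and without at least 1 other heart, with adjusted p of up to 0.133.

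**Figure D2:**
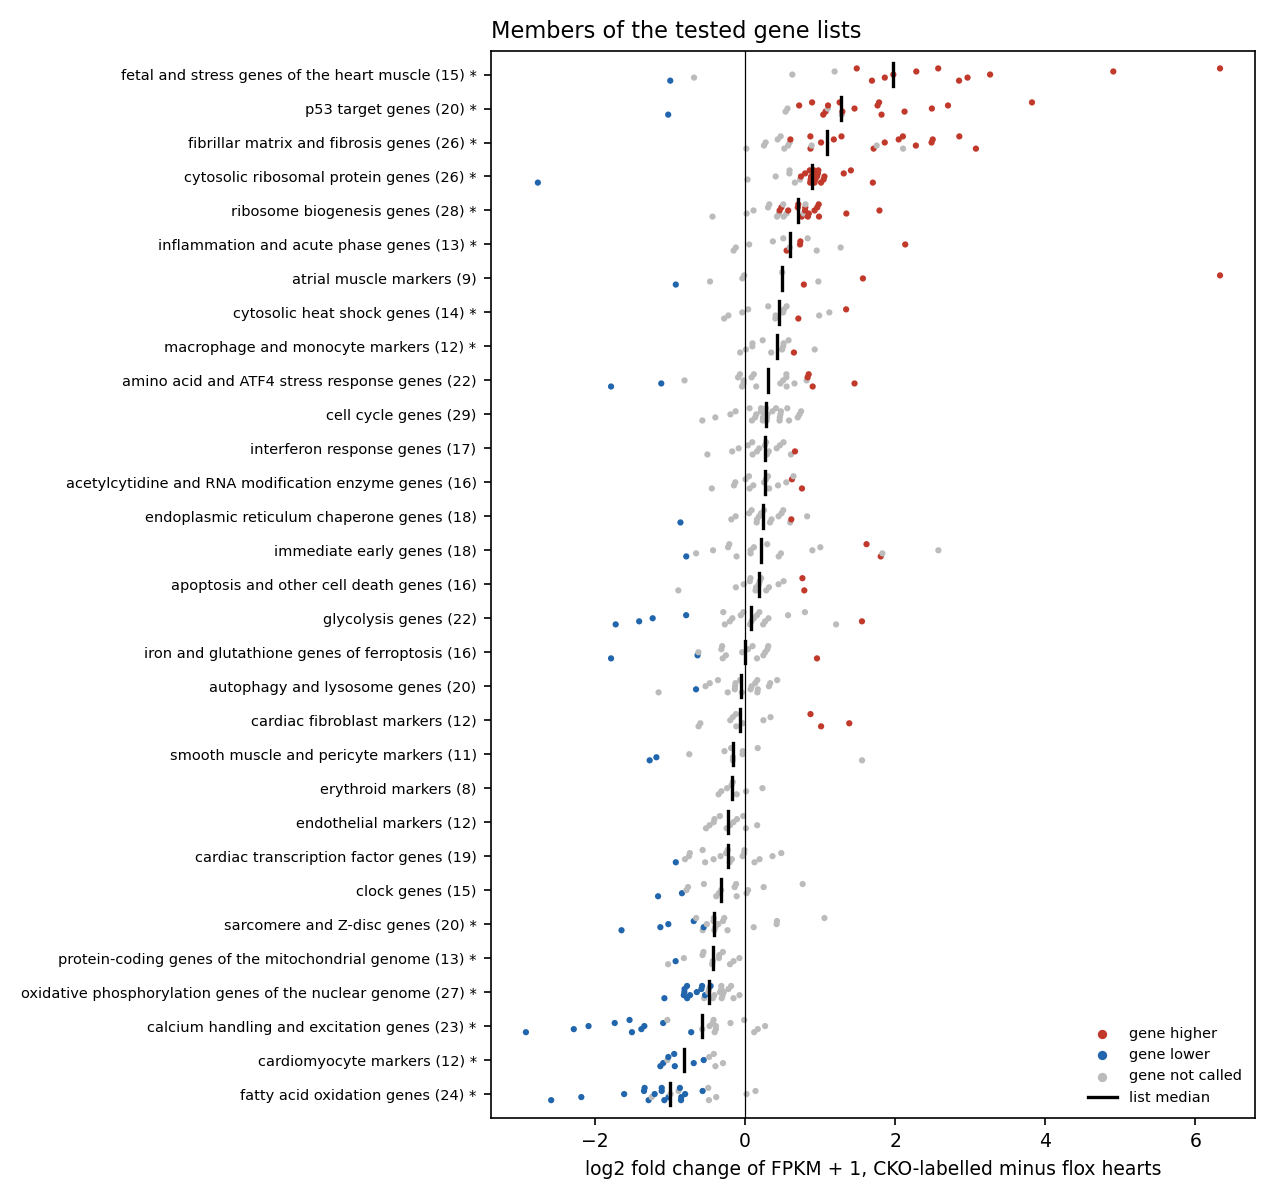
Each row is 1 of the 31 tested lists, with its number of measured genes in parentheses and an asterisk where camera at the preset correlation called it. Points are the log2 fold changes of FPKM + 1 of its genes (CKO-labelled minus flox hearts), in red where higher, in blue where lower and in grey where not called, and black bars are list medians. Medians run from −1.01 for fatty acid oxidation to 1.98 for the fetal and stress list.

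Genes of contraction, calcium handling and excitation were lower. Myh6, the main myosin heavy chain of the adult mouse heart (chromosome 14, 54941921 to 54966927), was at 5384 ± 1085 FPKM in flox and 2662 ± 615 FPKM in CKO-labelled hearts (SD, n = 3; log2 change −1.02 ± 0.25, limma adjusted p = 0.0345), and Atp2a2, the calcium pump of the sarcoplasmic reticulum, at 2191 ± 505 and 869 ± 231 FPKM (−1.34 ± 0.27, limma adjusted p = 0.0207). Of 20 sarcomere and Z-disc genes, 5 fell and 15 were not called (6 down and 1 up adjusted over the list alone), at a median of −0.41 (camera adjusted p = 0.0051; adjusted p = 0.423 with an estimated correlation). Tcap (−1.65 ± 0.41) and Tnnt2 (−1.13 ± 0.21) fell most. Of 23 calcium handling and excitation genes, 10 fell and 13 were not called (13 down adjusted over the list alone), at a median of −0.57 (camera adjusted p = 2.5e-06; adjusted p = 0.423 with an estimated correlation). Kcnip2, a subunit of transient outward potassium channels, fell from 62.0 ± 2.76 to 8.69 ± 6.75 FPKM (−2.92 ± 0.42, limma adjusted p = 0.00819), Kcnd2, a pore-forming subunit of the same channels, by a log2 change of −2.09 ± 0.27, and Kcnj3, an inward rectifier, by −2.28 ± 0.23. Calls of these 3 channel genes held without each heart in turn, but those of Atp2a2 (flox replicates 1 and 2), Tnnt2 (also CKO replicate 3), Myh6, Tcap and Pln (also CKO replicates 1 and 3) were lost when 1 heart was left out, with adjusted p of up to 0.134. Myh6 and Pln, at −1.09 ± 0.23, overlap other measured genes in the annotation, which limits their counts where strand is not used. The same limit holds for Nppa, Cdkn1a, Nhp2, Wdr43, Ckm and Per3. With quantile normalization, the sarcomere list was not called (adjusted p = 0.158, 0.0051 with the deposited scaling).

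Fatty acid oxidation and nuclear oxidative phosphorylation genes were lower as lists, and glycolysis genes were not. Cpt2, an enzyme that brings fatty acids into mitochondria, went from 99.1 ± 18.1 to 32.2 ± 9.14 FPKM (log2 change −1.61 ± 0.23, limma adjusted p = 0.00819). Ucp3, a mitochondrial carrier, fell by a log2 change of −2.18 ± 0.56. Of 24 fatty acid oxidation genes, 16 fell and 8 were not called (21 down adjusted over the list alone), at a median of −1.01 (camera adjusted p = 4.1e-10; adjusted p = 0.423 with an estimated correlation). Of 27 nuclear oxidative phosphorylation genes, 12 fell and 15 were not called (17 down adjusted over the list alone), at a median of −0.48 (camera adjusted p = 1.0e-08; adjusted p = 0.423 with an estimated correlation). Cox7a1 (−1.08 ± 0.19), Atp5a1 (−0.82 ± 0.15) and Sdhd (−0.81 ± 0.14) fell most. Of 13 protein-coding genes of the mitochondrial genome, mt-Co2 alone was called (−0.93 ± 0.24; 2 down adjusted over the list alone), at a list median of −0.43 (camera adjusted p = 0.00783; adjusted p = 0.423 with an estimated correlation), and the list was not called with quantile normalization (median −0.09, adjusted p = 0.272) or without a filter (adjusted p = 0.102). Mitochondrial-genome reads made up 15.6 ± 1.29% of counts in flox and 13.1 ± 1.37% in CKO-labelled hearts. The glycolysis list of 22 gene entries, in which Aldoa has 2, was not called (camera adjusted p = 0.690), with 1 entry higher, 4 lower and 17 not called, and 2 higher and 4 lower adjusted over the list alone. The list's median was 0.07 and its mean −0.03. Within it, the muscle enolase Eno3 fell from 748 ± 59.2 to 229 ± 52.1 FPKM (−1.73 ± 0.19), the insulin-regulated glucose transporter Slc2a4 fell by a log2 change of −1.41 ± 0.20, and Slc2a1, the basal glucose transporter, rose by 1.56 ± 0.32. The other called falls were Pfkm (−1.23) and Ldhb (−0.79), named after their values were seen. The calls of Cpt2, Eno3 and Slc2a4 held without each heart in turn, while those of Ucp3, mt-Co2, Slc2a1, Atp5a1, Sdhd and Cox7a1 were lost without flox replicate 1 and, except Cox7a1, without other single hearts, with adjusted p of up to 0.130.

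**Figure D3:**
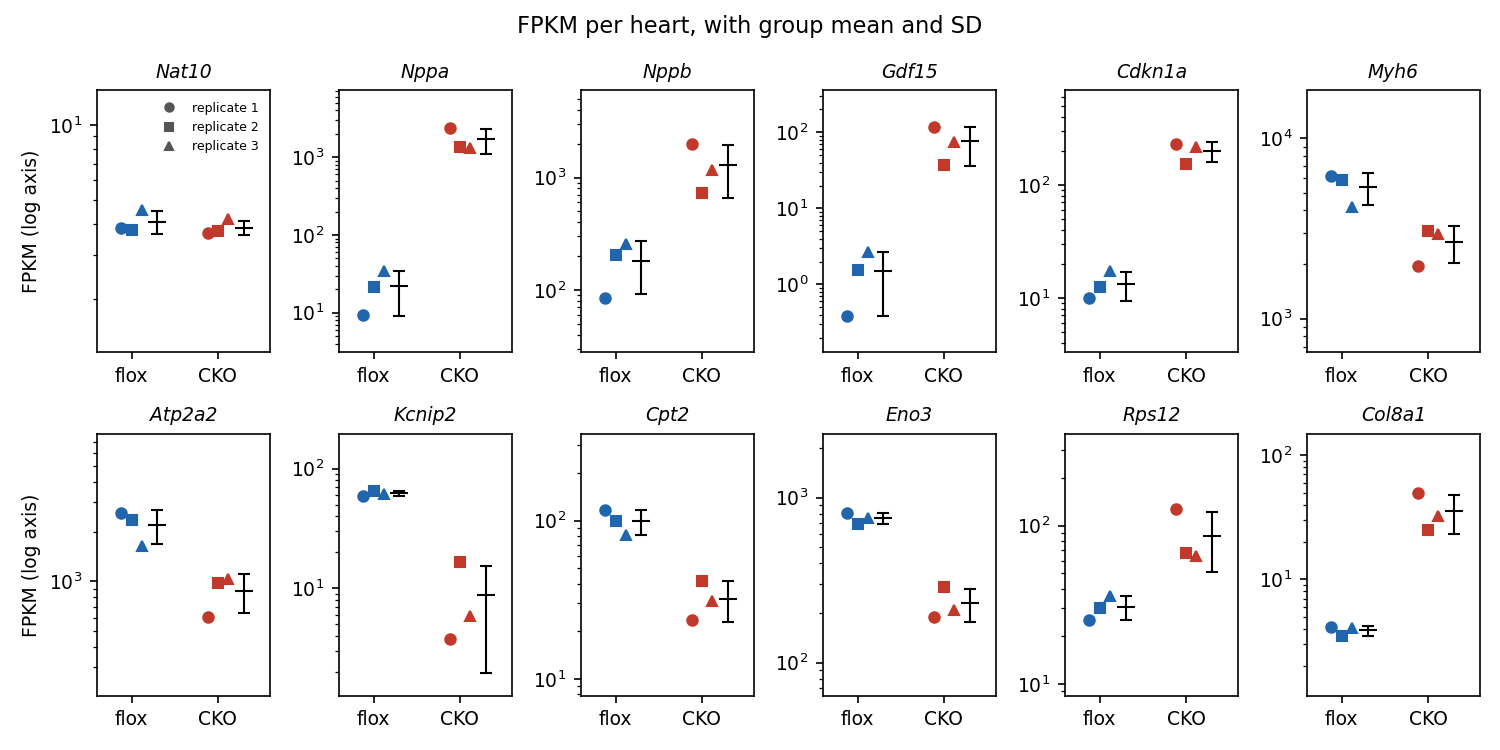
FPKM of 12 named genes in each of the 6 hearts, on log axes. Marker shapes stand for the replicate number, and horizontal bars with whiskers are the mean and SD of 3 hearts. The 3 CKO-labelled hearts lie apart from the 3 flox hearts for each gene except Nat10, for instance at 1696 ± 609 against 21.9 ± 12.7 FPKM for Nppa.

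Of the remaining lists, cytosolic heat shock genes passed (2 of 14 rose, 12 not called, 2 adjusted over the list alone, median 0.46, camera adjusted p = 0.0169; adjusted p = 0.531 with an estimated correlation), with Hsp90aa1 at 1.35 ± 0.26 and Hspb8 at 0.71 ± 0.19. The list was not called with a filter of 5 FPKM (adjusted p = 0.0993). Of 29 cell cycle genes 0 were called by limma at the adjusted threshold (1 at an unadjusted p under 0.05), and the list was not called (median 0.28, camera adjusted p = 0.222). This rested on flox replicate 3, without which the median was 0.85 and the list was called (adjusted p = 2.7e-09). Amino acid and ATF4 response genes went both ways, with 4 of 22 higher, among them Sesn2 (1.46 ± 0.15), and 2 lower, Chac1 (−1.79 ± 0.35) and Aldh1l2 (−1.12 ± 0.19), and the list was not called (camera adjusted p = 0.132). Immediate early genes were not called as a list (camera adjusted p = 0.235), although Ier3 (1.81 ± 0.38) and Myc (1.62 ± 0.30) rose and Dusp1 fell (−0.78 ± 0.21). That list was called without flox replicate 1 (adjusted p = 0.0418) or CKO replicate 2 (adjusted p = 0.0191). The call of Sesn2 held without each heart in turn, while those of Hsp90aa1, Hspb8, Chac1, Aldh1l2, Ier3, Myc and Dusp1 were lost without flox replicate 1 and at least 1 other heart, with adjusted p of up to 0.168. The lists of chaperones of the endoplasmic reticulum, interferon response, cell death, ferroptosis, autophagy, cardiac transcription factor, clock and RNA modification genes were not called, with camera adjusted p of 0.0523, 0.0782, 0.0697, 0.606, 0.569, 0.0943, 0.0707 and 0.0549. Their called members were Pdia4 (0.62) and Herpud1 (−0.86) among 18 chaperone genes, Ifit2 (0.66) among 17 interferon response genes, the survival genes Bcl2 (0.79) and Bcl2l1 (0.76) among 16 cell death genes, and Hmox1 (0.96), Steap3 (−0.63) and Chac1 among 16 ferroptosis genes. Wipi1 (−0.65) was called among 20 autophagy genes, Tbx5 among 19 cardiac transcription factor genes, Hlf (−1.16) and Per3 (−0.84) among 15 clock genes, and Pus1 (0.76) and Tsr3 (0.62) among 16 RNA modification genes (log2 changes). Each of these calls was lost without flox replicate 1 and without at least 1 other heart, with adjusted p of up to 0.168. Of these lists, leaving out 1 heart brought calls for interferon response (flox replicate 3, adjusted p = 0.0464; CKO replicate 1, 0.0145; CKO replicate 3, 0.0244) and clock genes (flox replicate 3, 0.0174; CKO replicate 2, 0.0438; CKO replicate 3, 0.0464). The same held for cardiac transcription factor (flox replicate 3, 0.0293; CKO replicate 3, 0.0404), RNA modification (flox replicate 2, 0.0294; CKO replicate 2, 0.0316), chaperone (CKO replicate 2, 0.00479) and cell death genes (flox replicate 3, 0.0179). In all, 14 of 31 lists were called, 8 up and 6 down, 0 of them with an estimated correlation (lowest adjusted p = 0.363) and 10 by fry. The 4 that fry did not call were the sarcomere (adjusted p = 0.05002), ribosomal protein (0.0586), heat shock (0.119) and macrophage lists (0.0517). The remaining 8 lists had under 5 measured genes and were not tested. Of these, Dbh and Tubb3 (neuron markers), Cidea (adipocyte), Ckm (skeletal and heart muscle) and Hopx, a lung list member that heart muscle also expresses, were called, at log2 changes of −1.29, 1.53, −0.51, −0.94 and −1.62, and of these only the call of Hopx held without each heart in turn.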

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

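Scaling by total counts and removal of trends with gene length or GC content were alternatives chosen after the data were seen. The number of genes called ran from 364 to 1794 when 1 heart was left out, against 1761 with all hearts, and those called at least 2-fold from 307 to 893, against 666. Fewer hearts were tested in these fits. Without a filter, 641 genes were called (351 at least 2-fold), with more genes tested (28188). Array weights called 2784. The groups of 4940 genes did not overlap. With the replicate number as a block, 541 genes were called and 423 at least 2-fold. Deviations of same-numbered hearts correlated between −0.28 and −0.14, and 0 of 6 hearts correlated best with its own number. These values show no pairing by number, but 3 hearts per group are too few to exclude one. The count of lists called was 14, and 0 with an estimated correlation. It ran from 15 to 19 when 1 heart was left out. The log2 change of Nat10, −0.06 as reported, was not called under any alternative and changed sign with TPM (0.0645), array weights (0.000845), scaling by total counts (0.0538) and the length trend removed (0.0141), and ran from −0.101 to 0.0129 when 1 heart was left out, and the cause was not tested. Its mean lies under the filter of 5 FPKM, so that setting gave no value. Fabp4, at −0.03 and not called, changed sign with TPM (0.12) and scaling by total counts (0.11), and ran from −0.0884 to 0.0927 when 1 heart was left out. Of 79 called named genes, 29 kept their call without each heart in turn, and 50 lost it without flox replicate 1. The calls lost were 49 without a filter, 42 with the block, 5 with TPM, 5 with scaling by total counts, 3 with voom, 3 without a trend and at most 2 with each other setting on all hearts, with 0 changing sign. Called genes under the filter of 5 FPKM had no value with that setting. The median-ratio alternative kept all 1761 calls and moved those at least 2-fold to 664, because the deposited values already carry that scaling. Sex as a covariate was not run. In the simulation 20 of 100 2-fold changes were called. It changed far fewer genes than were called in the data, so this share does not measure the power of the real comparison. Changes that were not called still cannot be read as absent.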

Other observations

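The tests of a swap of hearts, of other Nat10 RNA, of the share of muscle RNA and of isoform pairs were chosen after the results were seen. Outside the fixed list, 53 more protein-coding genes with ribosomal protein symbols were measured, of which 40 rose and 0 fell, at a median log2 change of 0.92. Myh7 stood at 1.33 ± 0.220% of the Myh6 FPKM in flox and 1.33 ± 0.158% in CKO-labelled hearts (SD, n = 3; exact permutation p = 1). Myh6 reads assigned to Myh7 would also give a constant ratio, and this was not tested. The 10 most abundant genes held 20.7 ± 1.90% of counts in flox and 16.1 ± 1.73% in CKO-labelled hearts.

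Splits of the 6 hearts into 3 and 3 number 10, too few for a share under 0.05. In the real split 1761 genes were called, and the highest of the other splits called 3, with 1 split as large as the real one, itself. For genes changed at least 2-fold the real value was 666 and the highest other 3, again with 1 split as large. For lists the real value was 14 and the highest other 21, and 4 of the 10 splits gave as many, so the number of lists called by camera at the preset correlation does not set the genotype split apart.

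Nat10 was at a like level in both groups. A swap of hearts between the 2 groups would make another split of the 6 hearts the true one, but each other split called at most 3 genes against 1761 for the labels. This argues against such a swap where expression follows genotype, and does not exclude an exchange of whole groups. Nat10 RNA of other heart cells, or RNA that lost only the deleted part, may keep the whole-gene value up. Gene-level values cannot decide it, and the lower 95% bound of the log2 change was −0.33. Of the 28 ribosome biogenesis genes, 1 had a lower change than Nat10, and whether a rise shared with these genes offsets a loss of Nat10 RNA stays open.

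Heart muscle genes were lower. If the other cell types kept their proportions to each other, a lower share of muscle RNA would raise the markers of each of them alike. Macrophage markers changed by 0.59 ± 0.12 more than endothelial markers (difference of mean log2 values per heart, SE). The endothelial score itself changed by −0.23 ± 0.05. These 2 scores were the highest and lowest of the tested non-muscle lists and were picked after the results were seen. The SE of their gap therefore understates its uncertainty. Fibroblast, smooth muscle and erythroid scores lay between, at 0.17 ± 0.22, −0.21 ± 0.12 and −0.14 ± 0.30. The macrophage list also lost its camera call without flox replicate 2. The scores did not rise alike, but whether the other cell types kept their proportions was not tested, so the gap cannot decide on a lower share. A lower share together with a changed balance of the other cell types, a change within macrophages, and a real fall of muscle transcripts stay open as untested hypotheses.

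Ribosomal protein genes were higher, at a median log2 change of 0.89. Removing the trend with gene length, which was −0.155 across genes as Spearman's rho (genes are not independent replicates), left a median of 0.81, and removing the trend with GC content, where rho was −0.0143 and little was there to remove, left 0.90, with the list still called. No single heart carried the pattern, since the lowest median without 1 heart was 0.66, without CKO replicate 1. These tests argue against length and a single library as the whole cause, and the GC correction adds little. A difference that goes with the genotype label, reads shared with pseudogenes, and RNA from other cell types stay open for this list, as untested.

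A hypothesis of a change in isoform balance was that isoforms of heart or striated muscle fell against a paired isoform. The paired isoform was not ubiquitous in every pair, as for Ldhb to Ldha, Tnni3 to Tnni1 and Pygm to Pygb. Of these, Ldhb to Ldha (−1.10 ± 0.26, adjusted p = 0.0128 by limma on the log2 ratio) was among the lower ratios counted below. In 14 measured pairs, limma on the log2 ratio per heart gave 8 lower ratios past the adjusted threshold and 0 higher. The largest were Rpl3l to Rpl3 (−3.35 ± 0.51, adjusted p = 0.00248), Slc2a4 to Slc2a1 (−2.97 ± 0.49, adjusted p = 0.00256) and Eno3 to Eno1 (−2.30 ± 0.33, adjusted p = 0.00248), each lower in 3 of 3 CKO-labelled hearts. Among the paired genes of the 8 lower ratios, limma called only Slc2a1 by itself, which rose. The lower ratios thus partly restate falls of muscle genes given above. A lower share of muscle RNA would also lower such ratios, which was not tested. Cpt1b to Cpt1a (0.04 ± 0.21) and Pygm to Pygb (−0.12 ± 0.20) did not pass. All 8 lay among the 12 pairs whose first-named member is in a fixed list, whose values had been seen when the pairs were chosen. The test was first run on all 14 pairs and was narrowed after that result was seen. Of the 2 pairs outside the lists, 0 passed, which is too few to decide on a change in isoform balance.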
